A study of Mus musculus with 5 samples.

How the data were processed

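The series measured gene expression by RNA sequencing in 3 tumours of mice in which a Cre recombinase under the tyrosine hydroxylase promoter (Th-Cre) switched on a MYC transgene, and in normal pancreas of 2 wild-type littermates. The labels give no batch, sex, age or library kit, and no statement of whether the libraries were stranded or selected for polyadenylated RNA. The numbers that open the sample descriptions run consecutively within each tissue and lie far apart between the tissues. No label says what these numbers stand for. Per the labels' protocols, the normal pancreas was perfused with an RNase-inhibiting solution before it was taken out, and total RNA of both tissues was extracted with a column kit. The labels do not say that the tumours were perfused in this way.

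Per the submitters' processing notes, Trim Galore 0.60, STAR 2.7 and RSEM 1.31 were used with the builds mm10 and GRCm38. Settings and the annotation release are not given in the sources used here. The authors deposited estimated counts (expected counts) per gene, made with RSEM per the submitters' processing notes, which RSEM splits between genes that share reads and which need not be whole. They also deposited TPM values (transcript abundances), which RSEM computes from those counts and the effective length of each gene, so that every library sums to the same total. The effective length of each gene, a value of another kind in bases, comes from the same per-library files that the authors deposited and was used only for the length correction. A further deposited table of FPKM values was not used. The table held 55573 genes. The series tables and the per-library files held the same values, with a largest difference of 0. The 92 rows of synthetic spike-in sequences, all at 0 counts, were left out.

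Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The test was the quasi-likelihood test (glmQLFit, glmQLFTest) with TMM scaling, filterByExpr at its default settings and Benjamini-Hochberg adjustment over 16810 genes, with an adjusted p under 0.05 as the threshold. Positive log2 fold changes mean higher in tumour. The standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts relative to the TMM-scaled library size, as edgeR gives them. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which compares a list with all other genes, adjusted over 35 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Counts of list members are out of those tested. A gene near 0 in normal pancreas enters the test only through its tumour counts, so counts of rises among such genes are in part set by the filter. For hormones at equal granule gene level, the scaling factors came from the secretory granule and neuroendocrine list alone, as the median of ratios over the 27 members with counts in every library. Shares of counts were compared by a two-sided exact permutation test, for which 3 against 2 libraries give 10 splits and a smallest p of 0.1.

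The comparisons, the tests, the 35 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule names a fixed set of genes, the 8 protein-coding genes with the largest rise and the 8 with the largest fall (adjusted p under 0.05, mean log2 CPM of 5 or more, every tumour on the same side of both normal libraries), and per gene list up to 3 members with the smallest p. Genes outside the rule are named as chosen after their values were seen, and a few genes are not reported here. A gene at 0 counts in all libraries of a group is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of pooled counts is given with its 95% exact binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Coordinates are on GRCm38 from the GENCODE M21 annotation, whose gene identifiers agree, version included, with 55094 of the 55573 in the table.

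The total of estimated counts was 48848987 and 51669489 in normal pancreas replicates 1 and 2, and 15074489, 12601496 and 6611967 in tumour replicates 1, 2 and 3. The acinar enzymes, the other amylase genes and the gene 2210010C04Rik took 86.2% of the normal counts, so the normal libraries hold fewer counts for other genes than the total implies. The TMM factors were 0.271, 0.263, 2.5, 2.57 and 2.19. No pair of replicates agreed within sampling noise, with chi-square values per degree of freedom of 27.3 for the normal pair and 37.6 to 59 for the tumour pairs. The titles of tumour replicates 1 and 2 share the number 86 and that of replicate 3 has 114, and no label says whether a shared number means a shared animal. P-values therefore measure the spread between these samples, which may in part be technical.

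The tests were tried on simulated counts with a single mean per gene over all 5 libraries and their TMM-scaled sizes. Changes were up or down, in 67, 67 and 66 genes by 1, 2 and 4 on the log2 scale. The remaining genes were left unchanged, so the rates below do not cover the large difference in composition between these tissues. edgeR, on 15107 simulated genes, recovered 26.9% of genes changed by 1 on the log2 scale, 85.1% of those changed by 2 and 97% of those changed by 4, and called 0.0268% of unchanged genes. DESeq2 recovered 26.9%, 91% and 100% on 16810 genes. With limma on log2 values, 0%, 58.2% and 97% were recovered on 16788 genes. A simulated trend with gene length led to calls for 10.9% of 13274 unchanged protein-coding genes, and for 0.0753% once the trend was removed.

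The alternative settings fixed then were DESeq2 size factors, upper-quartile scaling, total counts only, TMM without the acinar lists, the DESeq2 1.42.0 test, limma with trend on log2(TPM + 1) and log2(TPM + 0.1), no low-count filter, a CPM of 1 or more in at least 2 libraries, protein-coding genes only, each library left out in turn, tumour replicates 1 and 2 summed, glmTreat against a fold change of 2, and other list tests and share definitions. Removal of each library's trend with gene length, and a wider acinar share, were chosen after seeing the data. So was a comparison of the ribosomal protein and oxidative phosphorylation lists with, for each member, the 20 protein-coding genes outside the lists nearest in length, or in length and mean log2 CPM, with 2000 bootstrap samples of the members. Bounds and ratios without a library keep the scaling of all 5 libraries. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

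Several families have near-identical copies between which reads may be split, and their single members are uncertain: the amylases, trypsinogens, elastases, kallikreins, Ins1 and Ins2, the haemoglobins, 7SL genes, histones and clustered protocadherins. Overlapping and antisense genes are uncertain too, since no use of strand is stated.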

Results

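RNA sequencing compared 3 tumours of Th-Cre:MYC mice with normal pancreas of 2 wild-type littermates. The mice carry MYC behind a transcriptional stop that Cre removes in cells that have used the tyrosine hydroxylase promoter, a gene of catecholamine-producing cells. The series title presents the animals as a neuroblastoma model, and its design text describes the tumours as tumours of the pancreas. The stated question was how expression differed between the tumours and normal pancreas. Library totals ran from 6611967 to 51669489 estimated counts, and both normal totals were larger than every tumour total. Outside the acinar lists and the other amylase genes the order was reversed. There every tumour library held more counts than either normal library, with the non-coding RNA described next included. The TMM-scaled library sizes were also larger in every tumour library than in either normal library.

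The libraries of the tissues differed in the RNA classes they held as well as in depth. Protein-coding genes took 99.3% ± 0.113 (SD, n = 2) of the counts in normal pancreas and 65.3% ± 3.13 (SD, n = 3) in tumour. The misc_RNA class, which holds the signal recognition particle RNA 7SL and the transcription regulator RNA 7SK, took 0.000741% ± 0.000597 (SD, n = 2) in normal pancreas and 23.5% ± 1.67 (SD, n = 3) in tumour. The exact permutation p was 0.1 for both shares, the smallest these libraries allow. The 7SL pair Rn7s1 and Rn7s2 held at most 0.00109% of a normal library and at least 19.6% of each tumour library. Mitochondrial rRNA, chosen after its values were seen, held 0.00889% and 0.00737% in normal pancreas and 2.31%, 2.52% and 3.60% in tumour. Yet the 13 mitochondrially encoded genes had a median log2 fold change of only 0.398 with total counts only. Together these values argue against tissue alone as the cause of the class difference. It separates the same libraries as tissue does, so for single genes the effects of its cause and of tissue cannot be told apart.

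**Figure D1:**
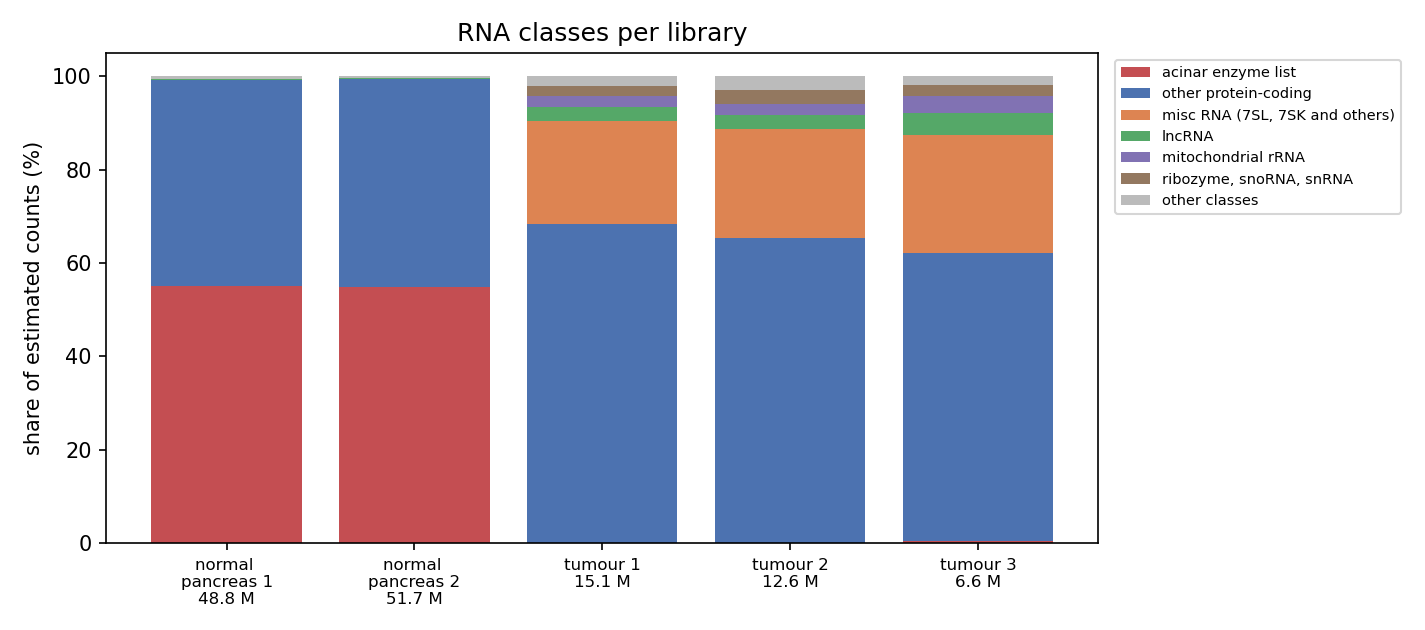
Share of estimated counts in percent (vertical axis) by RNA class for each of the 5 libraries, with each library's total under its name. The acinar enzyme list takes 54.96% of normal pancreas counts on average and at most 0.402% of any tumour library, and misc RNA takes 22.0% or more of each tumour library.

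The mouse gene for MYC was lower in the tumours, which carry a MYC transgene. Myc (ENSMUSG00000022346.15, chromosome 15, 61985391 to 61990374, + strand) was lower in every tumour, at 0.718, 1.46 and 1.11 CPM against 31.7 and 29.6 CPM in normal pancreas. It fell by 4.81 on the log2 scale (SE 0.28, edgeR adjusted p = 4.52e-05), and by 1.62 when libraries were scaled by total counts only. The labels do not give the species of the transgene, so its transcript may not be counted at the mouse gene, and these values do not measure it. Mycn, the MYC family member amplified in many human neuroblastomas, fell by 4.47 (SE 0.40, edgeR adjusted p = 0.000179). Mycl did not pass (log2 0.58, SE 0.75, edgeR adjusted p = 0.518), but passed as higher with total counts only (log2 3.69, edgeR adjusted p = 0.00261). Of 16 genes of the MYC network, 5 rose and 7 fell. Mga, which encodes a partner of MAX, rose by 3.02 (SE 0.21, edgeR adjusted p = 7.87e-05). The network had a median of 0.09 and a mean of 0.33 but a downward camera direction (adjusted p = 0.545).

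Digestive enzyme transcripts of the acinar cells, which make up most of the exocrine pancreas, were nearly missing from the tumours. The list of 26 enzymes took 54.96% ± 0.147 (SD, n = 2) of all counts in normal pancreas and 0.146% ± 0.222 (SD, n = 3) in tumour (exact permutation p = 0.1). Tumour replicate 3 held 0.402%, and without it the tumour mean was 0.0185%. Of the 26 enzymes, 24 fell and 2 did not pass the test, and 25 fell when adjusted over the list alone. The DESeq2 test called 13 lower. Ctrc, a chymotrypsin, fell by 12.71 on the log2 scale (SE 0.60, edgeR adjusted p = 2.86e-05). Cpa1, a carboxypeptidase, went from 158000 CPM ± 6348 (SD, n = 2) to 0.957, 0.372 and 98.5 CPM in the tumours (edgeR adjusted p = 0.0198), and the trypsinogen Prss2 from 116800 CPM ± 6698 (SD, n = 2) to 1.22, 0.0619 and 103 CPM (edgeR adjusted p = 0.0238). Without tumour replicate 1, 14 enzymes fell, and Cpa1 (adjusted p = 0.0607) and Prss2 (adjusted p = 0.0637) no longer passed edgeR's test. Prss2 also missed it without either normal library (adjusted p = 0.0576 and 0.0570).

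The other acinar genes fell with the enzymes, 19 of 19. Rab3d, a small GTPase of zymogen granules, fell by 3.32 on the log2 scale (SE 0.17, edgeR adjusted p = 3.42e-05), and did not pass with total counts only (log2 -0.15, edgeR adjusted p = 0.330). Bhlha15, a transcription factor of secretory cells, fell by 4.76 (SE 0.28, edgeR adjusted p = 4.68e-05). Gata4 was 2141-fold lower, with an interval of 732 to 10390, from 3 counts in all tumours, and 1186-fold without tumour replicate 1 or 1322-fold without tumour replicate 2. Camera called the enzymes (adjusted p = 8.18e-08) and the non-enzyme genes (adjusted p = 1.19e-11). With an estimated correlation neither list passed (adjusted p = 0.717 and 0.612). The 8 largest falls among abundant protein-coding genes were Rnase1, Hamp2, Klk1, Tmed11, Amy2a5, Amy2a4, Klk1b5 and Sostdc1. Hamp2, a hepcidin gene expressed in pancreas, had 0 counts in the tumours and was at least 4025-fold lower, or 2230-fold without tumour replicate 1 and 2485-fold without tumour replicate 2. The amylase Amy2a4 (edgeR adjusted p = 0.0421) lost its call without any 1 of 4 libraries, both normal ones and tumour replicates 1 and 2 (adjusted p = 0.0693 at the lowest and 0.140 at the highest), with protein-coding genes only (0.0557) and with tumour replicates 1 and 2 summed (0.0707). Amy2a5 lost it without tumour replicate 1 (edgeR adjusted p = 0.0563).

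Over all genes, 6587 were higher in tumour and 4669 lower, with 5554 not past the test. Among 14070 protein-coding genes, 4971 were higher and 4370 lower. In both normal libraries 1608 of the higher genes had 0 counts. The median log2 fold change of all genes was 0.38 with TMM, 0.51 with upper-quartile scaling and 3.55 with total counts only, so directions below are relative to a median that depends on the scaling. The higher genes made up 58.5% of the calls with TMM, 97.5% with total counts only, 62.5% with upper-quartile scaling, and 90.1% and 90.7% by limma on log2(TPM + 1) and log2(TPM + 0.1). With total counts only, the median of every list except the acinar lists was above 0. Against a fold change of 2, 4402 genes were higher and 2374 lower. Lower bounds against 0 counts in normal pancreas were 1.97 times smaller without normal pancreas replicate 1 and 2.03 times without replicate 2, since the floor depends on depth.

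Most islet hormone genes were higher in the tumours. Somatostatin (Sst, ENSMUSG00000004366.4, chromosome 16, 23889573 to 23890958, - strand), the hormone of islet delta cells, had 18310, 7464 and 14970 CPM in the tumours and 0.605 and 3.17 CPM in normal pancreas, a log2 rise of 12.81 (SE 1.66, edgeR adjusted p = 0.000798). Its share of counts was 3.25% ± 1.33 (SD, n = 3) in tumour and 4.98e-05% ± 4.73e-05 (SD, n = 2) in normal pancreas (exact permutation p = 0.2). Every tumour share (4.57%, 1.91% and 3.27%) was above both normal shares. The p is above 0.1 because the test compares means and the spread between tumours lets another split give a larger difference. Iapp, the islet amyloid peptide, rose by 9.13 (SE 0.68, edgeR adjusted p = 9.45e-05). Pancreatic polypeptide (Ppy) was 6686-fold higher, with an interval of 1851 to 55210, from 2 counts in normal pancreas. Of its 42086 tumour counts 38677 were in tumour replicate 1, without which the ratio was 978 (interval 270 to 8076), and without tumour replicate 2 it was 10260. Cck, the cholecystokinin gene, was at least 213-fold higher. Of 15 listed hormone genes 10 were tested, of which 8 rose, none fell and 2 did not pass. The median was 9.45, or 8.44 with genes at 0 in a group placed at their bound. Camera did not call the list (adjusted p = 0.0649), but called it as higher in 5 of 17 other settings, among them the DESeq2 test (0.000115) and the length trend removed (0.0436).

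The insulin genes did not pass the test. Ins1 had 16.7 and 14.4 CPM in normal pancreas and 19.0, 3.96 and 1.94 CPM in the tumours (edgeR adjusted p = 0.378), and Ins2 had 33.9 and 35.9 CPM against 30.03, 6.44 and 3.88 CPM (edgeR adjusted p = 0.162). Without tumour replicate 1 both passed as lower in edgeR (log2 -2.33 and -2.71, adjusted p = 0.0013 and 0.000236), and Ins2 also did with tumour replicates 1 and 2 summed (edgeR adjusted p = 0.0449). With total counts only Ins1 passed as higher (log2 2.34, edgeR adjusted p = 0.0446) and Ins2 did not pass (1.86, edgeR adjusted p = 0.0700). Glucagon (Gcg) had 421, 2.14 and 82.3 CPM in the tumours and 1.51 and 3.68 CPM in normal pancreas (log2 6.02, SE 2.09, edgeR adjusted p = 0.0395). Gcg did not pass without normal pancreas replicate 1 (edgeR adjusted p = 0.187) or 2 (0.147), or without tumour replicate 1 (0.0586) or 3 (0.05515), with log2 values from 3.999 to 6.81, nor by limma on log2(TPM + 1) (adjusted p = 0.0666). Ghrelin (Ghrl) was too low to test, with 5 counts in tumour replicate 1 and 0 elsewhere.

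At equal level of granule genes, 6 of 10 hormones were higher in tumour and 2 lower. In normal pancreas the median log2(CPM + 0.5) of the granule list was only 0.144 and -0.032, with 4 and 2 counts of Scg5 but 45 and 46 of Chga. The SEs below leave out the error of this reference. Granule genes with 0 counts in a library, among them Vgf and Syt4, are not in it, which can understate the granule rise and favour higher calls. Sst was higher by 6.45 on the log2 scale (SE 0.57) and Iapp by 2.85 (SE 0.40). Ins1 fell by 7.17 (SE 0.46) and Ins2 by 7.66 (SE 0.46), and Gcg did not pass (log2 -0.42, SE 0.53). Scaled on islet transcription factors instead, 8 were higher and 2 lower, with Ins1 falling by 2.57 (SE 0.66) and Ins2 by 3.04 (SE 0.62) and Gcg rising by 4.24 (SE 1.45, edgeR adjusted p = 0.0216). Without normal pancreas replicate 1, or without tumour replicate 1, 4 were higher, and without normal pancreas replicate 2, 3 were. Without tumour replicate 1 Gcg passed as lower (log2 -2.55, SE 0.51, edgeR adjusted p = 6.65e-07).

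**Figure D2:**
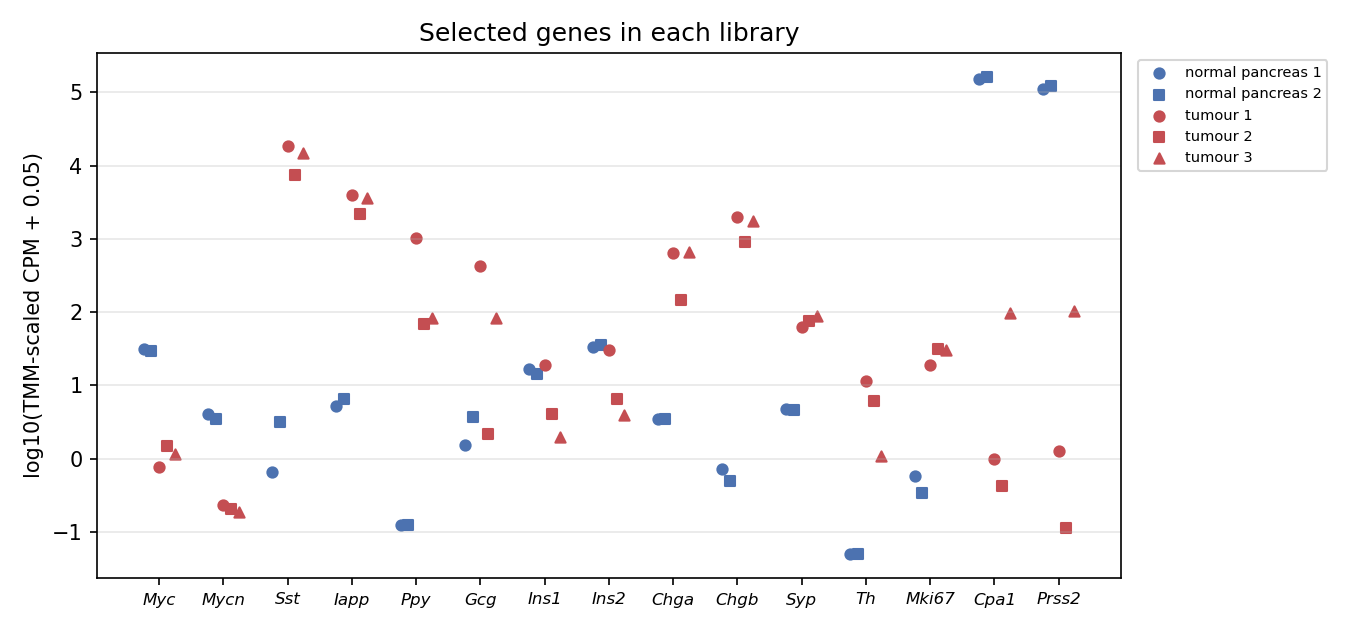
TMM-scaled CPM on a log10 axis, log10(CPM + 0.05), for 15 genes in the 5 libraries, blue for normal pancreas and red for tumour, 1 symbol per library. Sst, Iapp and Chgb are higher in all 3 tumours than in both normal libraries, Ins1 and Ins2 overlap or are lower, and Myc and Mycn are lower.

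Delta cell genes rose as a group, 15 of 16, with 1 not past the test. Nhs rose by 6.96 (SE 0.31, edgeR adjusted p = 2.49e-05), the LIM homeobox gene Isl1 by 7.54 (SE 0.42, edgeR adjusted p = 4.03e-05) and the receptor phosphatase gene Ptprz1 by 8.91 (SE 0.52, edgeR adjusted p = 4.54e-05). The median was 7.25, or 6.43 with bounds (camera adjusted p = 1.53e-07; adjusted p = 0.592 with an estimated correlation). Of 16 beta cell genes 8 rose and 1 fell, Ero1lb, by 5.06 (SE 0.40, edgeR adjusted p = 0.000117), an oxidase of the endoplasmic reticulum. Gjd2, a gap junction gene, was 64.1-fold higher, with an interval of 21.8 to 312, and 97.4-fold without normal pancreas replicate 1. Of 11 alpha cell genes 6 rose and 3 fell, with the glutamine transporter gene Slc38a5 falling by 10.78 (SE 0.32, edgeR adjusted p = 1.21e-05) and Gc rising by 3.56 (SE 0.27, edgeR adjusted p = 0.000104). Of 14 listed enteroendocrine and serotonin genes 7 were tested, of which 5 rose and 1 fell. Chgb, a granin, rose by 11.43 (SE 0.70, edgeR adjusted p = 5.08e-05), and Slc6a4, the serotonin transporter, fell by 5.74 (SE 0.61, edgeR adjusted p = 0.000366). The enteroendocrine median was 5.53, or 1.45 with bounds. Camera did not call the beta (adjusted p = 0.384, and 0.0381 upward without tumour replicate 2), alpha (0.999) or enteroendocrine list (0.458).

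Of 26 listed islet transcription factors 16 were tested, of which 11 rose and 2 fell, with 12 rising when adjusted over the list alone. Myt1 rose by 7.43 (SE 0.25, edgeR adjusted p = 1.66e-05). St18 was 517-fold higher, with an interval of 177 to 2507, and Pax6 1888-fold higher, with an interval of 339 to 74590. Without normal pancreas replicate 1 these ratios were 786 and 956, and without replicate 2 Pax6 was at least 310.5-fold higher. The median was 3.67 (camera adjusted p = 9.40e-07; adjusted p = 0.612 with an estimated correlation). Of 32 secretory granule and neuroendocrine genes, 26 rose, none fell and 6 did not pass. Chga (chromosome 12, 102554969 to 102565028, + strand), the granin used as a neuroendocrine marker, rose by 7.15 (SE 0.84, edgeR adjusted p = 0.000553), at 635, 147 and 664 CPM in the tumours. Syp, a vesicle membrane protein gene, rose by 4.01 (SE 0.21, edgeR adjusted p = 3.53e-05), Scg5 by 9.53 (SE 0.29, edgeR adjusted p = 1.21e-05) and Ncam1 by 8.22 (SE 0.30, edgeR adjusted p = 2.02e-05). Rab3c was 684-fold higher, with an interval of 189 to 5651. The median was 7.06 (camera adjusted p = 7.08e-20; adjusted p = 0.510 with an estimated correlation).

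Of 33 listed sympathoadrenal and neuroblastoma genes 18 were tested, of which 14 rose and 1, Mycn, fell. Genes near 0 in normal pancreas were tested only if the tumours had enough counts, so this majority is in part set by the filter. After Isl1, Dcx, a microtubule protein of young neurons, rose by 7.86 (SE 0.52, edgeR adjusted p = 6.75e-05), and Elavl4, a neuronal RNA-binding protein gene, was at least 150-fold higher. Th, the tyrosine hydroxylase gene whose promoter drives Cre, had 0 counts in normal pancreas and 428, 194 and 15 counts in the tumours, at least 67.5-fold higher (edgeR adjusted p = 0.0104), or 39.96-fold without tumour replicate 1, at 11.4, 6.01 and 1.04 CPM. Dbh, the enzyme that makes noradrenaline, was not tested, with 0 counts in all 5 libraries, which for the tumours together allows up to 0.0356 CPM. The list median was 7.09, or 4.48 with bounds. Camera called the list (adjusted p = 0.00231), and it did not pass with an estimated correlation (adjusted p = 0.592), with total counts only (0.845) or on log2(TPM + 1) (0.471) and log2(TPM + 0.1) (0.223). Of 14 listed neural crest and Schwann markers 7 were tested, of which 5 rose and 2 fell. Erbb3 fell by 2.16 (SE 0.25, edgeR adjusted p = 0.000508) and Ednrb rose by 1.23 (SE 0.20, edgeR adjusted p = 0.00214), and camera did not call the list (adjusted p = 0.894). Erbb3 was higher with total counts only, and did not pass limma's test on either TPM scale (adjusted p = 0.0719 and 0.0804).

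Brain and synapse genes outside islets rose in 17 of 19 cases. Unc13a rose by 8.38 (SE 0.29, edgeR adjusted p = 1.75e-05), the splicing factor gene Celf3 by 6.51 (SE 0.26, edgeR adjusted p = 2.26e-05), and the glutamate receptor gene Gria2 was at least 419-fold higher. The median was 6.96, or 5.97 with bounds (camera adjusted p = 1.78e-11; adjusted p = 0.510 with an estimated correlation). Of the 8 largest rises among abundant protein-coding genes, 7 had 0 counts in normal pancreas. Lower bounds were 3536-fold for the opioid precursor gene Pdyn, 1195-fold for the neuropeptide precursor gene Vgf, 1079-fold for Syt4, 810-fold for Dpp6, 765-fold for the guanylate cyclase receptor gene Gucy2c, 654-fold for Celsr3 and 559-fold for Spock1. Sst was the other. Of the 33385 tumour counts of Pdyn 29112 were in tumour replicate 1, and its bound was 817-fold without that library and 5575-fold without tumour replicate 2.

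Cell cycle genes rose in 38 of 42 cases and none fell. The proliferation marker Mki67 rose by 6.01 (SE 0.39, edgeR adjusted p = 6.29e-05), at 19.2, 31.0 and 30.3 CPM in the tumours, the replication helicase gene Mcm6 by 3.42 (SE 0.25, edgeR adjusted p = 8.64e-05) and the topoisomerase gene Top2a by 5.43 (SE 0.43, edgeR adjusted p = 0.000121). The median was 3.80, or 3.77 with bounds (camera adjusted p = 2.33e-06; adjusted p = 0.717 with an estimated correlation). Of 18 cell cycle inhibitors and tumour suppressors 6 rose and 6 fell (camera adjusted p = 0.999). The chromatin remodeller gene Atrx rose by 2.13 (SE 0.17, edgeR adjusted p = 0.000123) and Trp53 by 1.30 (SE 0.16, edgeR adjusted p = 0.000664). Men1, a tumour suppressor of endocrine tissue, fell by 1.06 (SE 0.14, edgeR adjusted p = 0.000995) but was higher with total counts only, and on the TPM scales it did not pass. Cdkn2a was at least 6.88-fold higher. Of 23 p53 target genes 6 rose and 9 fell (camera adjusted p = 0.188), with Btg2 falling by 1.58 (SE 0.14, edgeR adjusted p = 0.00019) and Plk2 by 3.09 (SE 0.28, edgeR adjusted p = 0.000199). With total counts only Btg2 was higher and Plk2 did not pass (log2 0.072, edgeR adjusted p = 0.786), and Btg2 did not pass limma's test on either TPM scale (adjusted p = 0.542 and 0.541).

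MYC target and ribosome biogenesis genes moved both ways, with 20 of 47 rising and 8 falling (median 0.24, camera adjusted p = 0.537). With total counts only all 47 rose (median 3.42). Camera called the list as higher there (adjusted p = 0.00584) and on log2(TPM + 1) (0.0110) and log2(TPM + 0.1) (0.0302), 3 of 17 other settings. Tert, the telomerase catalytic gene, rose by 4.75 (SE 0.37, edgeR adjusted p = 0.000115), Rrp1b by 2.12 (SE 0.19, edgeR adjusted p = 0.000177) and Utp20 by 1.56 (SE 0.15, edgeR adjusted p = 0.000249). Of 18 polycomb and chromatin genes 8 rose and 3 fell (camera adjusted p = 0.537, and 0.0121 upward with total counts only), including rises of the DNA methyltransferase genes Dnmt1 by 2.77 (SE 0.19, edgeR adjusted p = 7.21e-05) and Dnmt3a by 1.59 (SE 0.15, edgeR adjusted p = 0.000238).

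Cytoplasmic ribosomal protein genes fell in 45 of 47 cases with TMM (46 adjusted over the list alone), but 47 of 47 were higher with total counts only. Their median lay 1.73 below that of all genes under TMM, and 23 of 47 fell once the trend with gene length was removed. Rpl28 fell by 2.29 (SE 0.17, edgeR adjusted p = 0.000106) and Rpl11 by 1.69 (SE 0.17, edgeR adjusted p = 0.000279). Neither passed limma's test on log2(TPM + 1) (log2 -0.046 and -0.44, adjusted p = 0.886 and 0.135) or log2(TPM + 0.1), and on both scales 3 ribosomal protein genes rose and 1 fell. Nuclear oxidative phosphorylation genes fell in 23 of 28 cases (25 adjusted over the list alone), 28 of 28 were higher with total counts only, and 16 fell with the length trend removed. On log2(TPM + 1) 11 rose and 2 fell by limma's test. Sdhb fell by 2.43 (SE 0.17, edgeR adjusted p = 7.19e-05). Of 13 mitochondrially encoded genes 9 fell and 1 rose (10 falling adjusted over the list alone), and with total counts only 5 rose and 3 fell. The respiratory chain gene mt-Co2 fell by 5.72 (SE 0.40, edgeR adjusted p = 7.79e-05). Endoplasmic reticulum folding genes fell in 18 of 25 cases and rose in 4, and with total counts only 4 fell and 17 rose. Dnajb11 fell by 3.19 (SE 0.15, edgeR adjusted p = 2.92e-05), with no call with total counts only (log2 -0.011, edgeR adjusted p = 0.939), and the stress-response gene Ddit3 fell by 3.78 (SE 0.18, edgeR adjusted p = 2.92e-05). Against genes outside the lists matched on length alone, chosen after the values were seen, the ribosomal median differed by -0.56 (95% bootstrap interval -0.68 to -0.30) and the oxidative phosphorylation median by -0.52 (-0.81 to -0.30). With matching on length and mean abundance they differed by 0.23 (0.05 to 0.47) and 0.014 (-0.34 to 0.41). The tumour libraries, in which these lists were lower under TMM, are the ones with 22.0% or more of counts in misc_RNA. Camera called the ribosomal (adjusted p = 6.78e-09), oxidative phosphorylation (8.88e-06), mitochondrial (0.00022) and folding lists (8.18e-08). With an estimated correlation none of the 4 passed (adjusted p = 0.717, 0.717, 0.717 and 0.612). Camera lost the oxidative phosphorylation call with total counts only (adjusted p = 0.992) and on log2(TPM + 1) (0.0553).

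Glycolysis genes rose in 9 of 19 cases and fell in 1, with 8 rising when adjusted over the list alone (camera adjusted p = 0.169, and called as higher in 3 of 17 other settings, 0.00683 at the lowest). The glucose transporter gene Slc2a3 rose by 6.78 (SE 0.49, edgeR adjusted p = 8.61e-05) and the enolase Eno1 by 1.25 (SE 0.14, edgeR adjusted p = 0.000443). Of 21 hypoxia and angiogenesis genes 9 rose and 4 fell (camera adjusted p = 0.999), with Ndrg1 falling by 3.78 (SE 0.14, edgeR adjusted p = 2.02e-05), Ddit4 falling by 2.46 (SE 0.14, edgeR adjusted p = 3.95e-05) and Angpt2 rising by 3.74 (SE 0.29, edgeR adjusted p = 0.000107). Ddit4 was higher with total counts only. Of 19 stress and immediate early genes 8 rose and 4 fell (camera adjusted p = 0.999). Junb rose by 2.06 (SE 0.17, edgeR adjusted p = 0.00013) and Jund fell by 1.25 (SE 0.12, edgeR adjusted p = 0.000277), the latter higher with total counts only and not past limma's test on either TPM scale.

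Among markers of other cell types, fibroblast, stellate and matrix genes rose in 17 of 24 cases and fell in 3. Acta2, the smooth muscle actin, rose by 3.45 (SE 0.25, edgeR adjusted p = 8.91e-05) and the pericyte receptor gene Pdgfrb by 2.58 (SE 0.19, edgeR adjusted p = 9.60e-05). Camera called this list (adjusted p = 0.00475), and not with an estimated correlation (adjusted p = 0.717). Of 18 duct markers 4 rose and 7 fell, and camera did not call the list (adjusted p = 0.0649) but called it as lower in 7 of 17 other settings (0.000301 with total counts only, 0.0101 with the DESeq2 test). Muc1 fell by 9.498 (SE 0.26, edgeR adjusted p = 1.21e-05) while Krt19 fell by 5.92 (SE 0.38, edgeR adjusted p = 5.98e-05) and Krt7 rose by 3.12 (SE 0.18, edgeR adjusted p = 4.29e-05). Of 17 endothelial markers 8 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.545), with Egfl7 rising by 1.55 (SE 0.14, edgeR adjusted p = 0.00021). Of 20 myeloid markers 6 rose and 1 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.665), and Itgax was 28.0-fold higher, with an interval of 9.46 to 137, and 42.5-fold without normal pancreas replicate 1. Of the 4 T and NK cell markers tested, 0 passed edgeR's adjusted test, 0 had an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.936). Scaled by total counts only, 3 were higher, among them Lck and Il7r (edgeR adjusted p = 0.00272 and 0.0111), and Lck also was by limma on log2(TPM + 1) (adjusted p = 0.0321) and log2(TPM + 0.1) (0.00924). Of 10 B and plasma cell markers 2 rose and none fell, and 0 passed in edgeR adjusted over the list alone, while 2 had an unadjusted p under 0.05 and DESeq2 called 4 (camera adjusted p = 0.872). Scaled by total counts only, 8 rose, while camera, which compares them with other genes, called the list as lower (adjusted p = 0.00272), and without tumour replicate 2, 1 of 8 tested rose and 3 fell. The 2 that rose with TMM were Jchain (edgeR adjusted p = 0.0156) and Igkc (edgeR adjusted p = 0.042), with 2261 and 20278 of their 2942 and 24012 tumour counts in tumour replicate 2. Jchain lost its call without either normal library (adjusted p = 0.0557 and 0.105), as did Igkc (0.112 and 0.199), which also lost it without tumour replicate 2 (0.0505).

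Of 24 MHC and interferon genes 1 rose, Usp18, by 3.09 (SE 0.34, edgeR adjusted p = 0.000407), and 5 fell. Adjusted over the list alone 1 rose and 1 fell. Tap2 fell by 1.78 (SE 0.31, edgeR adjusted p = 0.00273) but was higher with total counts only, and did not pass limma's test on either TPM scale (adjusted p = 0.381 and 0.340). The median of this list was 0.27 and camera's direction was down (adjusted p = 0.800, and 0.0443 with total counts only). Of 11 adipocyte markers 4 rose and 1 fell (0 and 1 adjusted over the list alone), and their median of 7.12, 3.06 with bounds, contrasts in sign with camera's direction, down (adjusted p = 0.999, and 0.00409 with total counts only). The lipase gene Lpl fell by 2.93 (SE 0.23, edgeR adjusted p = 0.000108) and did not pass with total counts only (log2 0.27, edgeR adjusted p = 0.354). Of 8 hepatocyte and gut markers tested 6 rose and 1 fell (camera adjusted p = 0.147). Serpina1a was 583-fold higher, with an interval of 161 to 4816, or 295-fold without normal pancreas replicate 1 and at least 192-fold without replicate 2. Vil1 rose by 5.42 (SE 0.46, edgeR adjusted p = 0.000144) and the intestinal homeobox gene Cdx2 was at least 34.7-fold higher. Erythroid genes rose in 6 of 6 cases, with Hbb-bt rising by 4.49 (SE 0.66, edgeR adjusted p = 0.00141), and camera did not call the list (adjusted p = 0.0649), but called it as higher in 8 of 17 other settings (0.0068 at the lowest). The labels' protocols describe perfusion of the normal pancreas only, so for the erythroid genes handling and tissue cannot be told apart. For lists without a second count, adjustment over the list alone gave the same numbers.

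Some members that went against the majority of their list were chosen here after their values were seen, and their directions are those under TMM. The mitochondrial gene that rose was mt-Nd6, and the folding genes that rose were Pdia3, Pdia4, Canx and Ero1l. The fibroblast and matrix genes that fell were Col6a2, Dcn and Pdgfra. The alpha cell genes that fell beside Slc38a5 were Ttr and Slc7a2, and the glycolysis gene that fell was Hk1. The endothelial markers that fell were Tek and Plvap, and the myeloid marker that fell was Cd14. The adipocyte markers that rose, Adipoq, Retn, Cfd and Cidea, had 0 counts in normal pancreas, and Cidea lost its call in edgeR without either normal library (adjusted p = 0.0714 and 0.0718).

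**Figure D3:**
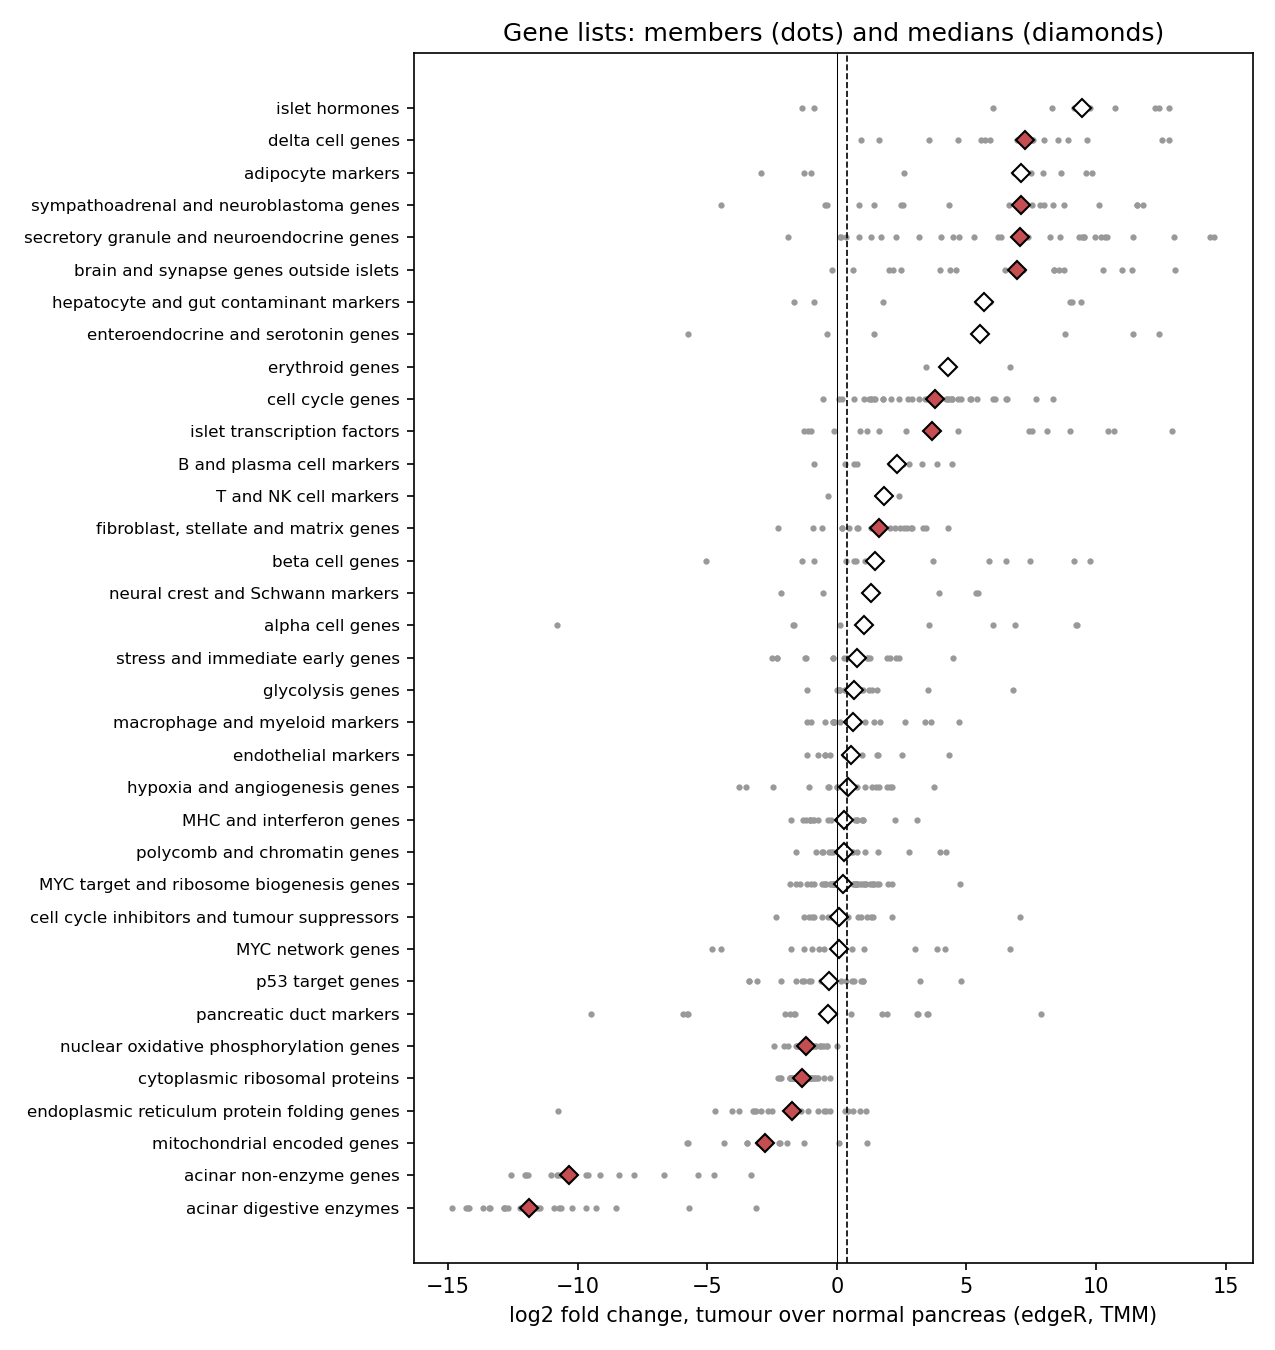
Log2 fold change of tumour over normal pancreas (horizontal axis) for the tested members of the 35 gene lists (grey dots) and the list medians (diamonds, filled red where camera at the preset correlation gave an adjusted p under 0.05). Granule genes have a median of 7.06 and acinar enzymes one of -11.87 around the median of all genes (dashed line, 0.38), genes at 0 in a group are drawn at fitted values, and with total counts only the ribosomal, oxidative phosphorylation, mitochondrial and folding medians lie above 0.

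The tumours differed from one another in several hormones, for which values are given without a test since 1 of the title numbers has a single library. Ppy had 1028, 68.4 and 83.2 CPM in tumour replicates 1, 2 and 3, and Pdyn 774, 27.8 and 234 CPM. Acinar transcripts were highest in replicate 3, at 98.5 CPM of Cpa1. Mki67 ranged from 19.2 to 31.0 CPM.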

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

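Removal of the length trend and the wider acinar share were chosen after seeing the data. Camera's 13 calls gave 7 lists higher and 6 lower, and 0 and 0 with an estimated correlation, where the smallest adjusted p was 0.510 and 2 lists had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 14 higher and 9 lower. Directions of single genes and the split of calls depend on scaling. The acinar enzymes, the other amylases and 2210010C04Rik took 86.2% of normal and 0.183% of tumour counts. With total counts only, or on TPM, this lowers the share left for every other gene in normal pancreas. Rises seen only under those settings can therefore come from composition alone. Otherwise the cause was not tested for the changes below unless stated. Myc was lower under all 17 other settings run, from -5.15 to -1.62 on the log2 scale.

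With total counts only, 15681 genes were higher and 398 lower. Distinct list members were 563 higher and 59 lower, against 269 and 207 with TMM. Log2 values turned positive for Ins1 (2.34), Ins2 (1.86), Erbb3 (1.014), Rpl28 (0.89), Rpl11 (1.49), Btg2 (1.61), Plk2 (0.072), Men1 (2.13), Ddit4 (0.72), Sdhb (0.74), Atp5j (1.64), Tap2 (1.41), Lpl (0.27) and Jund (1.93), all past the test except Ins2, Plk2 and Lpl, and Rab3d, Dnajb11, Herpud1 (-0.058) and mt-Atp8 (-0.29) lost their calls. Members higher and lower became 47 and 0 for ribosomal proteins, 17 and 4 for folding, 5 and 3 for mitochondrial and 28 and 0 for oxidative phosphorylation genes. Members lower became 0 for islet transcription factors and for fibroblast genes.

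On log2(TPM + 1), limma gave 10665 genes higher and 1173 lower and 83 list members lower, and Ins1 (0.021), Men1 (0.26), Atp5j (0.084) and Jund (0.19) turned positive without passing. On log2(TPM + 0.1) it gave 11558 and 1192 genes, 407 and 83 list members, and positive values, also not past the test, for Men1 (0.32), Atp5j (0.086) and Jund (0.20). On both scales ribosomal proteins had 3 higher and 1 lower, folding genes 9 and 11, mitochondrial genes 2 higher, and islet transcription factors and fibroblast genes 0 lower. Oxidative phosphorylation genes had 11 and 10 higher, and 2 lower on each.

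The DESeq2 test called 13 acinar enzymes lower. Against a fold change of 2, 4402 genes were higher and 2374 lower. With the length trend removed, 1 ribosomal protein gene was higher and 23 were lower, 2 mitochondrial and 2 oxidative phosphorylation genes were higher, and 9493 of 9573 genes called both ways kept their direction. Summing tumour replicates 1 and 2 gave 4 islet transcription factors lower, and the CPM filter or protein-coding genes only gave 0 sympathoadrenal genes lower, where Mycn was tested in the other settings. The normal acinar share was 64.0% of TPM, 58.0% with the non-enzyme list and 86.2% with the other amylases and 2210010C04Rik.

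Leaving out 1 library, which with a normal library assumes that the lone one varies like the tumours, gave 4631 to 6581 genes higher and 3443 to 4823 lower. Mycl ranged from -0.16 (without normal pancreas replicate 2) to 2.11. Hormones higher at equal granule level were 3 to 6, the 3 without normal pancreas replicate 2. Acinar enzymes lower were 14 (without tumour replicate 1) to 26, folding genes higher 0 (without either normal library) to 4 and mitochondrial genes higher 0 (without normal pancreas replicate 2) to 1. Members lower were 1 to 2 for sympathoadrenal genes (2 without tumour replicate 1), 0 to 1 for brain genes (1 without tumour replicate 2) and 0 to 1 for granule genes (1 without tumour replicate 3).

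Of 1846 other values of named genes under these settings, 1779 kept direction and side of the threshold. Counts for the 22 lists camera did not call stayed within 1.5 times in 575 of 748 cases. No paired analysis was possible because the numbers in the tumour titles do not pair with those of the normal samples.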

Other observations

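The genes and families in this first paragraph were chosen after their values were seen. Clustered protocadherin genes, cell-surface proteins by which neurons tell themselves apart, rose in 12 of 12 tested alpha and 22 of 22 tested beta cluster members (median log2 8.05 and 5.33), with the same counts once the length trend was removed, and in 14 of 22 gamma members, or 10 with the trend removed. Pore-forming voltage-gated calcium channel genes rose in 9 of 9 cases (median 6.68). Reads may be split between the protocadherin copies, and the length correction left the medians of the alpha and beta clusters at 7.89 and 4.90. Somatostatin receptor genes moved apart: Sstr3 was at least 261-fold higher in tumour, and Sstr2, the receptor most used to image neuroendocrine tumours, fell by 5.69 (SE 0.46, edgeR adjusted p = 0.000121), at 17.3 and 21.8 CPM in normal pancreas and 0.505, 0.124 and 0.554 CPM in the tumours, and by 2.50 with total counts only. Sstr1 was 54.97-fold higher, with an interval of 9.74 to 2184, at least 9.28-fold without normal pancreas replicate 1 and 27.1-fold without replicate 2.

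Imprinted genes were also chosen after their values were seen. Peg3 rose by 9.60 (SE 0.73, edgeR adjusted p = 0.000103) and Impact by 4.74 (SE 0.31, edgeR adjusted p = 6.04e-05). Zdbf2 was 2094-fold higher, with an interval of 580 to 17290. Grb10 fell by 2.58 (SE 0.16, edgeR adjusted p = 4.99e-05) but was higher by 0.60 with total counts only, and Snrpn did not pass (edgeR adjusted p = 0.670). The hormone Pyy had 1838, 51.5 and 43.5 CPM in tumour replicates 1, 2 and 3, and 0.0756 and 0.663 CPM in normal pancreas. The ratio of Ins2 to Gcg counts was 22.4 and 9.74 in normal pancreas and 0.0713, 3.01 and 0.0471 in the tumours.

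The tests in this and the next 2 paragraphs, and Malat1, Neat1, Hist1h1c and Hist1h2bc, were chosen only after the results were seen. Short non-coding RNAs and most histone genes were higher in tumour. More dividing cells as the whole cause would raise histone genes about as much as other cell cycle genes. Of 62 histone family genes 54 rose and 5 fell (3 with the length trend removed). The family median of 7.55 lay 3.75 above the 3.80 of 42 cell cycle genes (permutation p = 0.0002 over genes, which are not independent replicates). Both are medians of fitted values, and none with bounds was computed for the histone family. Low normal counts may widen this gap, so its size cannot decide whether division is the whole cause. The misc_RNA share was at least 22.0% in every tumour and at most 0.00116% in normal pancreas. Malat1, a nuclear RNA without the usual poly(A) tail, had 3718 CPM ± 421 (SD, n = 3) against 4.34 CPM ± 0.925 (SD, n = 2). Neat1, another long non-coding RNA, rose by only 1.60 (SE 0.31, edgeR adjusted p = 0.00427). Hist1h1c fell by 2.46 (SE 0.16, edgeR adjusted p = 6.54e-05) and Hist1h2bc by 1.47 (SE 0.18, edgeR adjusted p = 0.000709). Both histone genes were higher, by 0.71 and 1.70, with total counts only. These values are compatible with a library preparation that kept RNA without a poly(A) tail in the tumour libraries only. The labels neither state nor exclude this hypothesis, and such a difference would coincide with tissue.

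Ribosomal protein and oxidative phosphorylation genes were lower relative to other genes. A trend with gene length may explain part of this: once it was removed, the ribosomal median relative to all genes went from -1.73 to -0.78 (95% bootstrap interval -0.95 to -0.63) and the oxidative phosphorylation median from -1.56 to -0.81 (-1.10 to -0.52). Both lists were still called by camera at the preset correlation of 0.01 (adjusted p = 0.0399 and 0.0448). Neither passed camera with an estimated correlation (adjusted p = 0.911 and 0.935, and 0.717 for both before). The correlations estimated before the removal were 0.848 and 0.734, far above the preset value. The bootstrap intervals likewise treat the members as independent, so these tests cannot decide whether length is the whole cause. Against protein-coding genes outside the lists matched on length alone, the medians differed by -0.56 (-0.68 to -0.30) and -0.52 (-0.81 to -0.30), and with matching on mean abundance too by 0.23 (0.05 to 0.47) and 0.014 (-0.34 to 0.41). With this match neither list was lower than its matched genes, and the ribosomal genes lay above theirs. The genes matched to the ribosomal list were less abundant, by 0.385 in median log2 CPM. Mean abundance includes the tumour values under test, so this match cannot decide whether length and abundance explain the fall. What would produce such a trend, the preparation or the tissue, stays open.

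Mouse Myc was lower in the tumours. Scaling as the cause is argued against by its value of -1.62 (edgeR adjusted p = 0.00352) with total counts only, the scaling that raised tumour values most. Loss of the acinar tissue may contribute, but Myc lay 5.53 above the acinar non-enzyme median of -10.34, a gap that other cells expressing Myc could leave, so this explanation cannot be told apart from a lower level within the tumour cells. Repression of the mouse gene by the transgene is a further hypothesis that was not tested.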
